A study of Mus musculus with 6 samples.

How the data were processed

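Total RNA was sequenced from 6 mouse Sertoli cell libraries, 3 from lines positive and 3 from lines negative for a GFP reporter on the Y chromosome. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, ribosomal RNA was removed, and strand-specific libraries were made by the dUTP method. The submitters' processing notes name Trimmomatic, HISAT2, StringTie and the genome build mm39, without versions. The strand setting used in assembly is not given in the sources used here, so genes that overlap on opposite strands are not told apart with certainty.

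Each library has a deposited table of the same 153503 transcripts, annotated ones and newly assembled ones. The authors' FPKM (fragments per kilobase of transcript, relative to the depth of the library) is given for each transcript, per the file headers. The deposited tables also hold mean per-base coverage. Coverage divided by FPKM was constant within each library and gave the total aligned bases, 8.25 to 11.8 Gb per library. No read counts were used, so no counting interval is given for any value.

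The FPKM of a gene was the sum over its transcripts. Unnamed isoforms at a locus with exactly 1 gene name on the same strand were added to that gene, unnamed loci kept their assembly identifier, and 1404 transcripts that fell under neither rule were left out. These held between 1.63% and 6.34% of the FPKM of a library. Libraries were scaled by the median of ratios over 12666 genes with a mean FPKM of at least 1. Genes whose longest transcript was under 200 nt (1205 of 53218) and genes with a mean scaled FPKM under 0.5 were left out, which left 15309 genes. Of these, 13767 had a symbol and 1527 were unnamed new loci.

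Values were tested as log2(scaled FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), GFP-positive minus GFP-negative, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Levels are mean scaled FPKM ± SD over 3 libraries. The 28 gene lists were fixed before the data were examined, and those with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Chromosomes were tested by camera in the same way. The mean log2 level of the Y single-copy genes was compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1.

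Genes are named by a rule also fixed before the data were examined. It takes every Y single-copy gene and X-linked partner in the tables, and the 12 largest rises and 12 largest falls among called genes with ordinary symbols whose groups did not overlap. From each list it takes up to 4 members past the threshold by adjusted p, or else the 2 with the highest mean. Genes named outside this rule were chosen after their values were seen, which the text says where it names them.

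The method was tested on simulated data for the same contrast over 15309 genes. It recovered 3 of 68 genes changed by 1 on the log2 scale (4.4%), 42 of 66 changed by 2 (63.6%) and 61 of 66 changed by 4 (92.4%), with 4 false calls among 110. Only these genes were changed, with noise drawn independently for each gene. The data gave 4639 calls, and with so many the adjusted threshold is less strict. There, changes near 1 could pass, such as Ndn (0.93) and Pcdhgb4 (-1.01). The recovered shares therefore do not carry over to the data.

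The count of called genes was recomputed under 26 alternatives, 20 planned and 6 added after the data were seen. They varied the pseudocount, the filter, the scaling, the variance model, library weights, the threshold, the gene definition and the libraries included. The added ones were named transcripts only, sums per assembled locus, removal of a trend with transcript length (a loess fit per library), removal of length and GC trends, removal of GFP-negative libraries 11 and M, and a gene-by-gene method for library weights. In addition, 13 tests of explanations were run, and the prediction of 1 of them was written after its result was seen. GC content came from transcripts of the mouse reference matched by identifier and was known for 89.8% of tested genes. Coordinates are those of the deposited tables (mm39), with no conversion between builds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, which also read the tables with pandas 2.3.3.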

Results

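Transcript levels were measured by total RNA sequencing in Sertoli cells, the somatic cells of the testis tubule that support germ cells. The 6 libraries came from lines positive for a GFP reporter on the Y chromosome (replicates 2, 4 and 7) or negative for it (replicates 9, 11 and M). The GFP-positive libraries held 11.2, 11.8 and 11.3 Gb of aligned bases and the GFP-negative libraries 10.02, 9.67 and 8.25 Gb. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The comparison asks how lines that express the reporter differ from lines that do not, first in the Y-linked genes around it. The GFP transcript itself was not analysed here.

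Y single-copy genes were on average higher in the GFP-positive libraries, but unevenly. Over the 6 Y single-copy genes above the filter, the mean log2 level was 2.66 ± 0.59 (SD, n = 3) in GFP-positive and 1.61 ± 0.42 in GFP-negative libraries. The difference of 1.05 (SE 0.42) had an exact permutation p of 0.1, the smallest the design allows. Uba1y, which encodes a ubiquitin-activating enzyme (chromosome Y, 818649 to 844224), rose from 0.3003 ± 0.043 to 3.75 ± 2.68 FPKM, a log2 change of 2.24 (SE 0.41, adjusted p = 0.00949). Ddx3y, which encodes an RNA helicase (chromosome Y, 1260771 to 1286629), rose from 3.41 ± 1.71 to 7.92 ± 2.34 FPKM, a log2 change of 1.15 (SE 0.35, adjusted p = 0.0396). The other members did not pass. The translation factor gene Eif2s3y had a log2 difference of 1.04 (adjusted p = 0.0803), Usp9y 1.35 (adjusted p = 0.0739), Uty 0.75 (adjusted p = 0.225) and the demethylase gene Kdm5d -0.22 (adjusted p = 0.551). Over all tested genes 2 of the 6 passed, and 4 did when adjusted over the list alone. The list did not pass in camera (adjusted p = 0.114). It did without GFP-positive 4 (0.0438), with no filter (0.0396), scaled to an equal sum of FPKM (0.0438), and with a trend in transcript length removed, alone (0.00798) or with GC content (0.0151). With no filter 10 genes were tested and 1 rose, with a median log2 change of 0.66, against 1.10 with the filter. Of those 10 genes, 4 had a mean of at least 0.5 FPKM in the GFP-negative and 6 in the GFP-positive libraries. The filter thus favoured genes that were high in the GFP-positive libraries, such as Uba1y and Usp9y, in the difference of 1.05.

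GFP-negative replicate 9 was close to the GFP-positive libraries in the broadly expressed Y genes. The mean log2 level of Ddx3y, Eif2s3y, Kdm5d and Uty was 3.42 in that library, against 2.23 and 2.52 in GFP-negative 11 and M and 3.82, 2.996 and 3.41 in GFP-positive 2, 4 and 7. Their group difference was 0.68 (SE 0.43, exact permutation p = 0.3). Usp9y ranged from 0.232 to 2.78 FPKM in the GFP-positive and from 0.0277 to 0.0384 FPKM in the GFP-negative libraries. Zfy1, Zfy2, Sry and Tspy-ps were below the filter, with Sry listed at 0 in 5 libraries. Of the Y ampliconic families, Rbmy rose by 1.63 on the log2 scale (SE 0.41, adjusted p = 0.0207), and near-identical copies share its reads. That call was lost with no filter, without GFP-positive 7 or GFP-negative M, and with the length trend removed (1.25, adjusted p = 0.0775). Ssty1, Ssty2, Sly, Srsy and Rbm31y, chosen after their values were seen, were listed at 0 in the libraries. The call of Ddx3y was lost when any library other than GFP-negative 9 was left out (adjusted p from 0.0532 to 0.149), with no filter (0.117), with FPKM as deposited (0.0642), scaled to an equal sum (log2 difference 0.25) and for named transcripts only (0.76), and that of Uba1y without GFP-negative M (adjusted p = 0.0540). Without GFP-negative 9, Eif2s3y (1.42) and Uty (1.25) also passed, and Usp9y did at a pseudocount of 0.1 (2.67), without GFP-positive 4 (1.81) and with the length trend removed (1.92). With each library scaled to an equal sum of FPKM, as in TPM, the list difference was 0.39 (exact permutation p = 0.7). On that scale the median of all genes stood at -0.86, against 0.03 in the main fit.

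**Figure D1:**
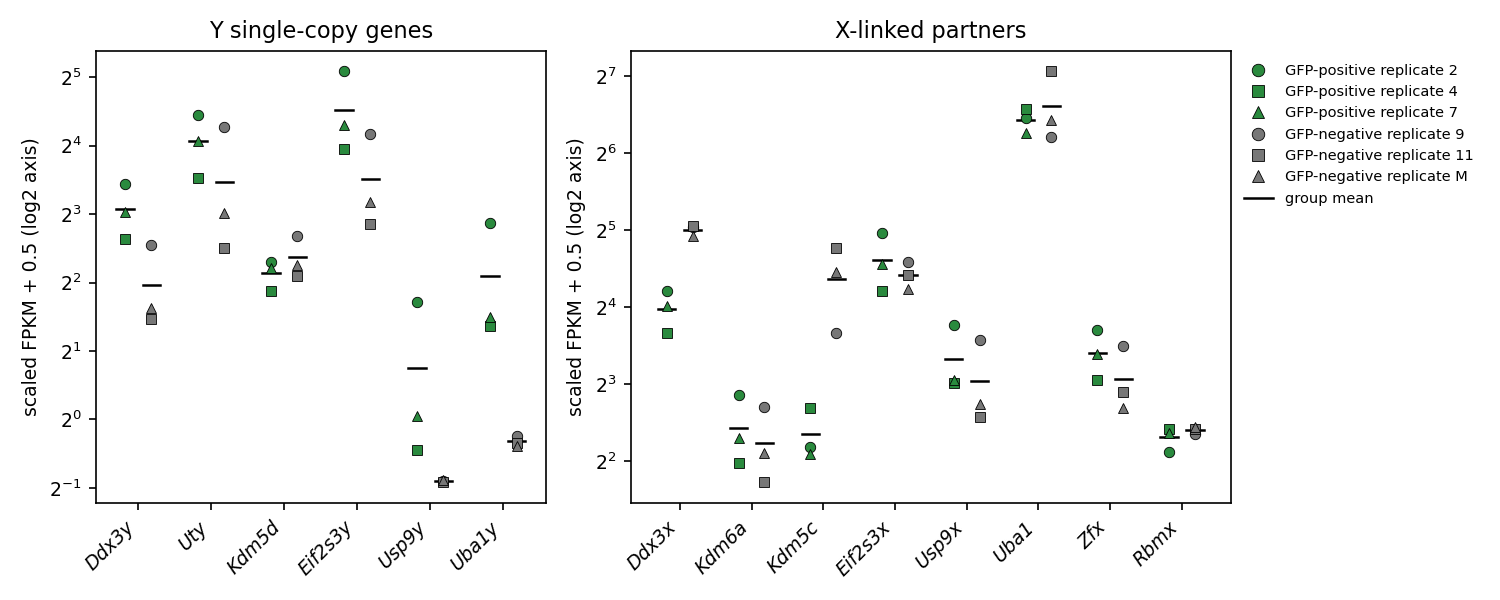
Scaled FPKM + 0.5 on a log2 axis for the tested Y single-copy genes (left) and X-linked partners (right) in each library, with bars at group means. Uba1y and Ddx3y lie higher in every GFP-positive library, while Kdm5c and Ddx3x lie lower.

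The X-linked partners of these genes did not rise. Of 8 tested, Kdm5c, the partner of Kdm5d, fell from 20.1 ± 7.30 to 4.59 ± 1.17 FPKM (log2 change -1.97, SE 0.33, adjusted p = 0.00805). Ddx3x, the partner of Ddx3y, fell from 31.6 ± 1.47 to 15.3 ± 2.95 FPKM (log2 change -1.04, SE 0.24, adjusted p = 0.0164), a call lost without GFP-positive 7 or GFP-negative M (adjusted p = 0.0730 and 0.0654) and with the length trend removed (-0.63, adjusted p = 0.0930). Eif2s3x (0.17), Kdm6a (0.20), Usp9x (0.31), Zfx (0.36), Uba1 (-0.14) and Rbmx (-0.10) did not pass, and Sox3 was below the filter. A high level in GFP-negative 9 was not particular to the Y genes. Kdm6a (6.02, 2.80 and 3.80 FPKM in GFP-negative 9, 11 and M), Usp9x (11.4, 5.45 and 6.21), Zfx and Eif2s3x were also highest there. Kdm5c, Uba1 and Rbmx were lowest in that library among the GFP-negative ones. The list median was 0.04 (camera adjusted p = 0.512).

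Across the genome, among 15309 tested genes, 4639 passed, 2541 higher and 2098 lower in the GFP-positive libraries (54.8% higher). Of the called genes with a symbol 1976 were higher and 2003 lower, and of the new loci 565 were higher and 94 lower. The largest rises were H2bc1 (log2 change 5.17), H2ac1 (5.02) and H3f4 (5.02), which encode histones but are not in the replication-dependent histone list below. They were followed by Tex101 (4.88), a germ cell surface protein gene, Rpl39l (4.77), Mael (4.57) and Dazl (4.36), and by Selenoh (3.86), Taf7l (3.84), H2bc27 (3.76), Tex19.1 (3.75) and Asz1 (3.50). H2bc1 rose from 0.971 ± 0.134 to 55.6 ± 23.7 FPKM (SE of the log2 change 0.33, adjusted p = 0.00106). It stood at 80.1, 32.8 and 53.8 FPKM in GFP-positive 2, 4 and 7. H2ac1, H3f4, Mael and Dazl were likewise highest in GFP-positive 2 and lowest in 4. By contrast, H2bc14, H2ac8, H4c1 and H2ac4 of the replication-dependent list were lowest in GFP-positive 2. The largest falls were Col1a1 (-4.21), which encodes a collagen I chain, Plec (-3.25), which encodes a cytoskeletal linker, Hspg2 (-3.14), Nfic (-3.0), Creb3l1 (-2.93) and Bcl2l1 (-2.88). Akap12 (-2.79), Itga5 (-2.75), Furin (-2.72), Rcn3 (-2.71), Ppp1r9b (-2.71) and Trim8 (-2.70) followed. Of these falls, Nfic, Bcl2l1, Itga5, Ppp1r9b and Trim8 did not pass without GFP-negative M, Itga5, Ppp1r9b and Trim8 without GFP-positive 7, Ppp1r9b without GFP-positive 2 or 4, and Bcl2l1, Itga5, Ppp1r9b and Trim8 with no filter. Plec fell from 49.3 ± 26.9 to 4.15 ± 1.25 FPKM (SE 0.48, adjusted p = 0.00643). Col1a1 was uneven among the GFP-negative libraries, at 9.99, 693.3 and 142.6 FPKM in 9, 11 and M. Its call was lost when any library other than GFP-negative 9 was left out (adjusted p from 0.0621 to 0.112), with no filter (0.145) and with the length trend removed (0.0712, at a log2 change of -3.73), with a log2 change of -2.86 without GFP-negative 11.

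The number of calls depended on single libraries. It was 2857, 2717 and 841 without GFP-positive 2, 4 and 7, and 6206, 3194 and 538 without GFP-negative 9, 11 and M. The 12 named rises passed in each of these 6 fits, whereas 6 of the 12 named falls passed without GFP-negative M and 8 without GFP-positive 7. Of all 91 named genes that passed, 38 passed in the same direction without GFP-negative M, 48 without GFP-positive 7, 61 with no filter, 71 with the length trend removed and 75 scaled to an equal sum. On the first principal component (64.8% of the variance) GFP-negative 9 lay at 20.6, between GFP-negative 11 and M (87.8 and 68.8) and the GFP-positive libraries (-66.5, -49.9 and -60.6). With 11 and M both left out no gene passed in limma, and 3677 had an unadjusted p under 0.05. Scaled to an equal sum, 7931 genes passed and 9.99% of them were higher, with the median of all genes at -0.86. That scaling moves all genes of a library alike, so counts of rises and falls under it say little about a single list.

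Germ cell markers rose together. Of 20 listed, 11 were tested and 9 rose, with none falling and a median log2 change of 2.25 (camera adjusted p = 1.59e-05, and adjusted p = 0.828 with an estimated correlation). The count was 9 when adjusted over the list alone. Among the 20 listed, 2 had a mean of at least 0.5 FPKM in the GFP-negative and 12 in the GFP-positive libraries. The filter thus favoured markers that were high in the GFP-positive libraries. With no filter 16 were tested and 4 rose, with none falling and a median of 1.99. Dazl, which encodes an RNA-binding protein of germ cells, rose from 0.527 ± 0.251 to 28.9 ± 29.8 FPKM (SE 0.64, adjusted p = 0.00628). Mael, of the piRNA pathway, rose from 0.360 ± 0.187 to 24.9 ± 21.4 FPKM (SE 0.54, adjusted p = 0.00492), and Tex101 from 0.150 ± 0.038 to 19.9 ± 9.48 FPKM (SE 0.34, adjusted p = 0.00106). Gfra1, the receptor subunit for GDNF on spermatogonia, rose from 0.310 ± 0.045 to 4.50 ± 2.59 FPKM (log2 change 2.51, SE 0.37, adjusted p = 0.00628). Dazl was uneven among the GFP-positive libraries, at 63.0, 7.89 and 15.9 FPKM in 2, 4 and 7. Prm1 and Prm2, the protamine genes of spermatids, were listed at 0 in the libraries (chosen after their values were seen). Without GFP-negative M, 4 of the markers passed.

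**Figure D2:**
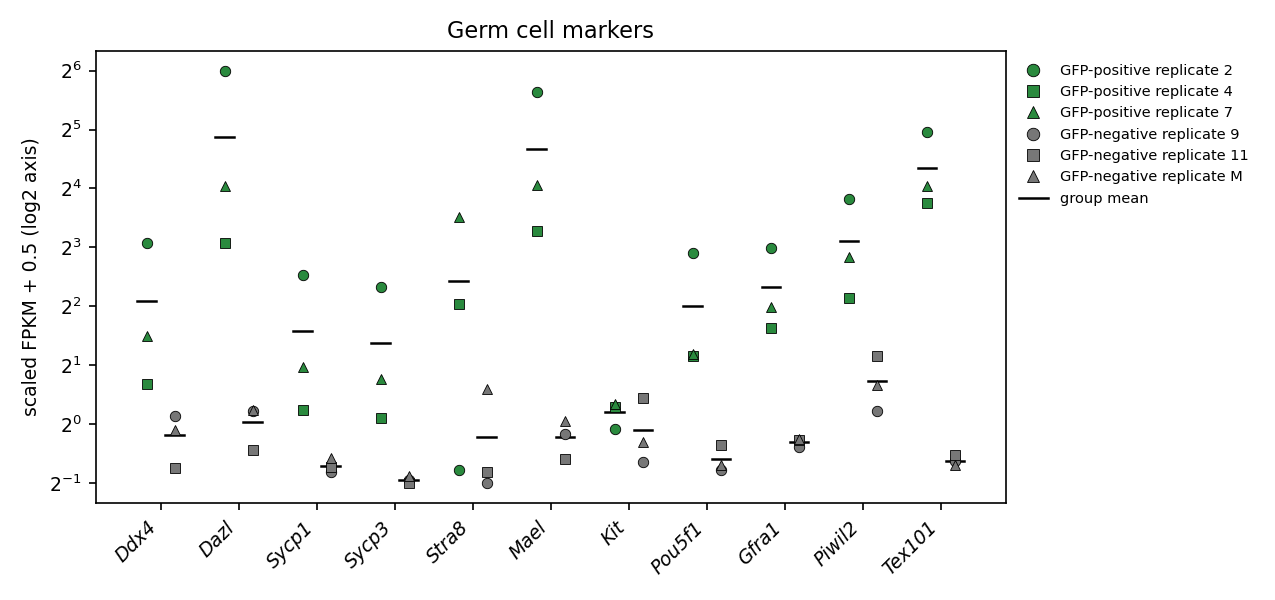
Scaled FPKM + 0.5 on a log2 axis for the 11 tested germ cell markers in each library, with bars at group means. Dazl, Mael, Gfra1 and Tex101 lie higher in every GFP-positive library, and Dazl and Mael are highest in replicate 2.

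Histone, ribosomal protein and cell division genes were also higher. Of 22 replication-dependent histone genes, 18 rose and 1 fell, with a median of 1.79 (camera adjusted p = 7.58e-08, and adjusted p = 0.828 with an estimated correlation). Scaled to an equal sum 9 rose and 1 fell, with a median of 0.78, and with the length trend removed 12 rose and 1 fell, with a median of 1.17. H2bc14 rose from 31.7 ± 2.31 to 263.2 ± 95.5 FPKM (log2 change 2.96, SE 0.33, adjusted p = 0.00424), followed by H2ac8 (2.68), H4c1 (2.49) and H2ac4 (2.39). The member that fell was H1f4, a linker histone gene chosen after its value was seen (-1.24, adjusted p = 0.0246). Of 26 proliferation genes, 10 rose and none fell, with a median of 1.09 (camera adjusted p = 0.00204, adjusted p = 0.828 with an estimated correlation, and fry adjusted p = 0.212). They included the cyclin genes Ccnb1 (2.56) and Ccna2 (2.26), the mitotic checkpoint gene Bub1 (1.85) and the spindle motor gene Kif11 (1.58). The proliferation call was lost without GFP-negative 9 (camera adjusted p = 0.153), and scaled to an equal sum 3 of its genes rose and 2 fell. Of 33 cytosolic ribosomal protein genes, 21 rose and none fell, with a median of 1.25 (camera adjusted p = 1.71e-05, and adjusted p = 0.828 with an estimated correlation), led by Rpl35 (1.95), Rpl15 (1.78), Rpl14 (1.76) and Rps3 (1.65). After quantile normalization 1 rose and 1 fell, with a median of 0.25, and the list did not pass (camera adjusted p = 0.474). Scaled to an equal sum 1 rose and 4 fell, and the list median of 0.23 stood 1.09 above that of all genes. Removing the length trend left 4 rising (median 0.62). Adjusted over each list alone, 19 histone genes rose and 1 fell, 10 proliferation genes rose, and 23 ribosomal protein genes rose. Without GFP-negative M, 6 histone, 4 proliferation and no ribosomal protein genes rose, and without GFP-positive 7 these counts were 10, 2 (Ccnb1 and Ccna2) and 3. Without GFP-positive 4, 5 proliferation and 9 ribosomal protein genes rose, and without GFP-positive 2, 11 ribosomal protein genes.

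Extracellular matrix and clustered protocadherin genes were lower. Of 34 matrix genes, 13 fell and none rose, with a median of -1.21 (camera adjusted p = 5.18e-06, adjusted p = 0.828 with an estimated correlation, and fry adjusted p = 0.0876). With the length trend removed 6 fell, with a median of -0.76, and scaled to an equal sum 28 fell. Hspg2, which encodes perlecan, fell from 122.8 ± 76.6 to 12.7 ± 6.17 FPKM (SE 0.54, adjusted p = 0.00852). Fn1, which encodes fibronectin, fell from 116.7 ± 63.9 to 20.7 ± 7.65 FPKM (log2 change -2.40, SE 0.43, adjusted p = 0.00912). The laminin gene Lamb1 (-1.58) and the fibrillin gene Fbn1 (-1.56) also fell. Of 16 protocadherin genes tested, 6 fell, with a median of -0.80 (camera adjusted p = 0.000419, and adjusted p = 0.828 with an estimated correlation). With the length trend removed 3 fell, with a median of -0.44 (camera adjusted p = 0.0371), and with length and GC trends removed the list did not pass (median -0.32, camera adjusted p = 0.0773). The called genes included Pcdhgb6 (-1.77), Pcdhgc3 (-1.64), Pcdhgc5 (-1.58) and Pcdhgb4 (-1.01), which share 3' exons and hence reads. Adjusted over each list alone, 15 matrix and 9 protocadherin genes fell. Without GFP-negative M, 3 matrix genes and 1 protocadherin gene (Pcdhgb6) fell, and without GFP-positive 7, 4 and 2 (Pcdhgb6 and Pcdhgc5). Lamb1 passed in neither fit. Without GFP-positive 2, 7 matrix genes fell. Among the GFP-negative libraries 9, 11 and M the matrix genes Hspg2 (51.5, 203.7 and 113.1 FPKM) and Fn1 (67.8, 189.1 and 93.3) were highest in 11 and lowest in 9. The same order held for Col1a1 and for the myoid, fibroblast and Leydig markers Myh11 (0.919, 17.3 and 2.33), Actg2 (5.44, 27.9 and 7.58), Pdgfrb (2.25, 28.6 and 6.82) and Insl3 (0.329, 3.57 and 0.833). It was not particular to these cell types. The first principal component had it too, as did the housekeeping genes Eef2 (223.4, 787.9 and 584.2) and Sdha (20.7, 37.0 and 34.0). The macrophage marker Lyz2 ran the other way (6.07, 2.16 and 4.60). Without GFP-negative 11 the matrix median was -0.90 and 11 genes fell.

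Sertoli markers moved in both directions. Of 39 tested, 5 rose and 7 fell, with a median of 0.19 and a mean of 0.06 (camera direction down, adjusted p = 0.724). Sox9, a transcription factor gene of Sertoli cell identity, fell from 46.3 ± 9.65 to 13.1 ± 4.79 FPKM (log2 change -1.82, SE 0.30, adjusted p = 0.00798). Inhba, an activin subunit gene (-1.47), and Gdnf, a growth factor gene (-1.25), also fell. Dmrt1 rose from 26.7 ± 2.79 to 58.0 ± 1.57 FPKM (log2 change 1.11, SE 0.22, adjusted p = 0.0116), a call lost without GFP-positive 7 or GFP-negative M (adjusted p = 0.0567 and 0.0553) and scaled to an equal sum (0.10). The call of Inhba was lost without GFP-negative M, and that of Gdnf without GFP-negative M or GFP-positive 7. Clu, at 1880 ± 822 and 1856 ± 1163 FPKM, and Wt1, at 18.8 ± 5.24 and 23.0 ± 4.88 FPKM in GFP-positive and GFP-negative libraries, did not pass (adjusted p = 0.803 and 0.450; both chosen after their values were seen). Without GFP-positive 7 no marker rose and 2 fell, without GFP-negative M none rose and 1 fell, and scaled to an equal sum 1 rose and 17 fell. Once the length trend was removed, 2 rose and 5 fell.

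Markers of other somatic cell types gave few calls. Among peritubular myoid markers, Myh11 (-2.49) and Actg2 (-2.18) fell and 8 did not pass (camera adjusted p = 0.106). None of them passed when adjusted over the list alone. The list median of -1.33 was -0.59 without GFP-positive 2, where 2 members rose and none fell. The list itself passed without GFP-positive 4 or 7 or GFP-negative M (camera adjusted p = 0.0263, 0.0367 and 0.0372) and after quantile normalization (0.0454). Among 10 fibroblast markers, Col1a1 and Pdgfrb (-2.42) fell (camera adjusted p = 0.412). Insl3 (-1.64) was the called gene among 8 Leydig markers, Lyz2 (-1.87) among 3 macrophage markers and Runx1 (-1.40) among 5 granulosa markers, and all 3 fell (camera adjusted p = 0.723, 0.510 and 0.510). Egfl7 (1.56) rose among 2 endothelial markers tested. Adjusted over the Leydig list alone, none fell. No call of this paragraph was kept without GFP-negative M, and without GFP-positive 7 those of Lyz2 and Runx1 were. Without GFP-positive 2 or 4 the calls of Myh11, Actg2, Col1a1, Pdgfrb, Insl3 and Egfl7 were lost, and without GFP-negative 11 those of Actg2 and Col1a1. With no filter that of Lyz2 was kept. The macrophage and leukocyte list then passed, with 14 genes tested and 2 lower (camera adjusted p = 0.0396). With the length trend removed Myh11 (-1.97), Col1a1 (-3.73), Pdgfrb (-1.98), Runx1 (-0.92) and Egfl7 (1.19) did not pass. Neither did Myh11 and Insl3 at a pseudocount of 1, Pdgfrb for named transcripts only (-1.77) or Egfl7 scaled to an equal sum (0.93).

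**Figure D3:**
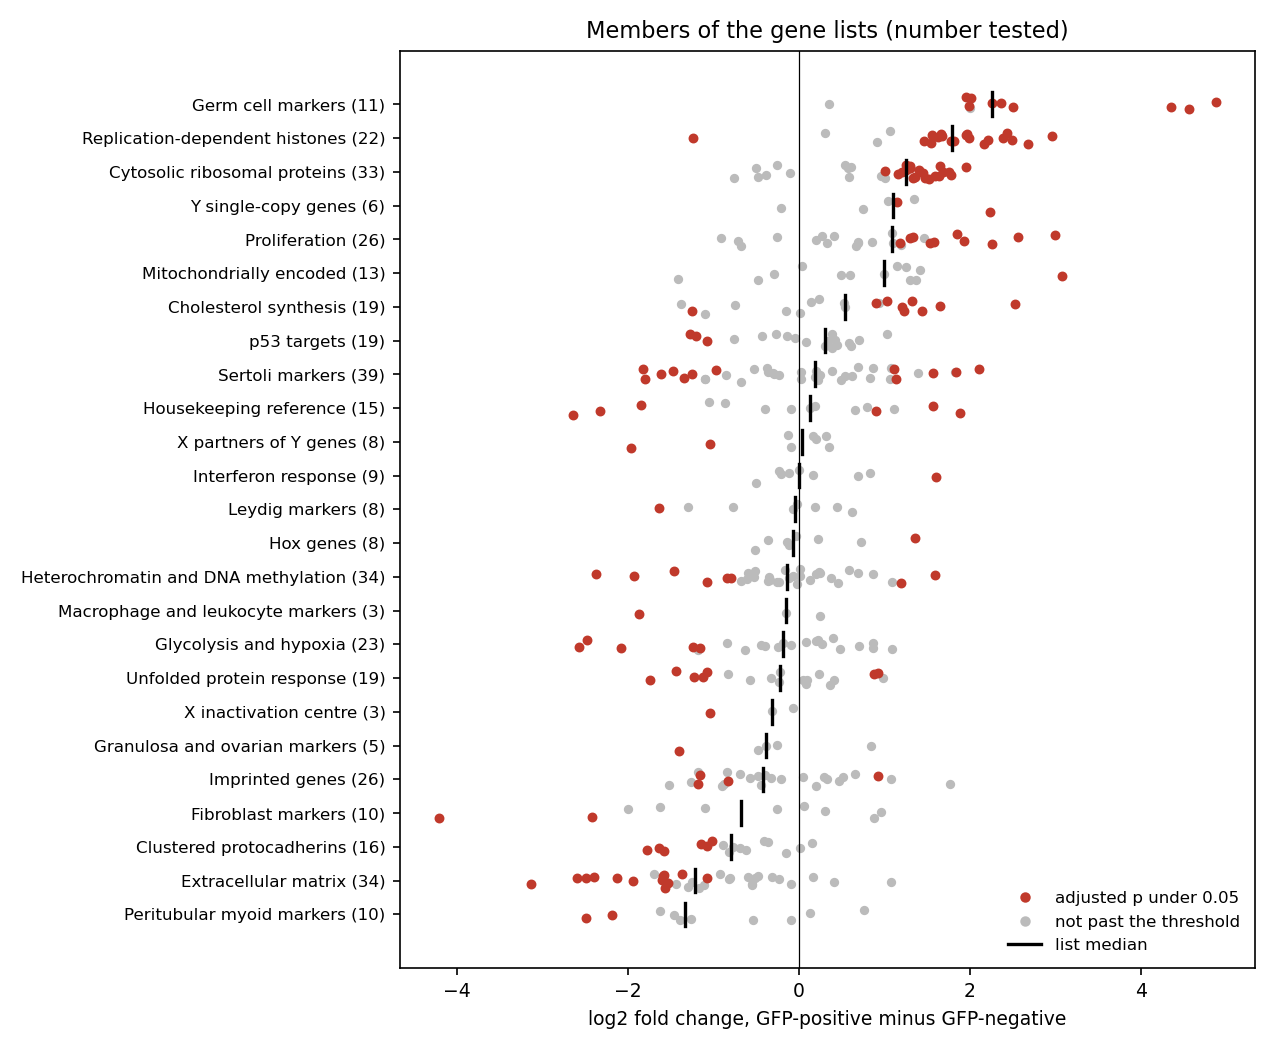
Log2 fold change (GFP-positive minus GFP-negative) of each tested member of the lists with at least 3 tested genes, red where the adjusted p is under 0.05, with a bar at each list median. Germ cell markers have the highest median (2.25) and peritubular myoid markers the lowest (-1.33).

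Metabolic and chromatin lists did not pass as lists in the main test. In cholesterol synthesis 8 of 19 genes rose and 1 fell (camera adjusted p = 0.106), with Fdft1 (2.53), Msmo1 (1.65), Pmvk (1.43) and Insig1 (1.32) higher. Scaled to an equal sum, 1 rose and 6 fell. The list passed without GFP-positive 2 (camera adjusted p = 0.0180), with no filter (0.0107), with the length trend removed (0.0324), with length and GC trends removed (0.0219) and without GFP-negative 11 and M. Without GFP-negative M, 1 of its genes rose. In the joint list of glycolysis and hypoxia genes 5 of 23 fell, including Pfkl (-2.57), Hk1 (-2.49), Hk2 (-2.08) and Vegfa (-1.24), with a camera adjusted p of 0.280. After quantile normalization the list passed with 8 genes lower (camera adjusted p = 0.0292). In the unfolded protein response 2 rose and 5 fell, with Herpud1 (-1.75), Ddit4 (-1.44), Vldlr (-1.12) and Sesn2 (-1.08) lower (camera adjusted p = 0.509), and with the length trend removed none rose and 2 fell. The p53 targets Zmat3 (-1.27), Cdkn1a (-1.21) and Sesn2 fell among 19 (camera adjusted p = 0.769). Among 34 genes of heterochromatin and DNA methylation, 2 rose and 6 fell. Tet3, a 5-methylcytosine oxidase gene (-2.37), Dnmt3a, a DNA methyltransferase gene (-1.93), and Jarid2 (-1.46) fell, and the histone methyltransferase gene Suv39h1 (1.2) rose (camera adjusted p = 0.375). Among 26 imprinted genes, Ndn (0.93) rose and Peg3 (-1.18), Igf2r (-1.16) and Airn (-0.83) fell (camera adjusted p = 0.375), although Ndn stood at -0.062 when libraries were scaled to an equal sum. Airn and Igf2r overlap on opposite strands and the strand setting is unknown, so their reads cannot be told apart with certainty and the calls are not separate. Adjusted over the list alone, 1 of the 3 fell. Xaf1 (1.61) rose among 9 interferon response genes, Hoxb6 (1.36) among 8 Hox genes and mt-Nd3 (3.08) among 13 mitochondrially encoded genes (camera adjusted p = 0.769, 0.769 and 0.510). Adjusted over the interferon and the mitochondrial list alone, none rose. The mitochondrial genes turned on the GFP-negative libraries: 6 rose and 1 fell without 9, and 2 fell and none rose without 11. Rlim (-1.04) fell among 3 genes of the X inactivation centre (camera adjusted p = 0.412), and so did Mid1 (-1.23), the tested pseudoautosomal or boundary gene. Of 15 housekeeping genes 3 rose and 3 fell, among them Polr2a (-2.64), Eef2 (-2.33), Sdha (-1.85) and Ppia (1.57; camera adjusted p = 0.769).

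Few calls of the paragraph above were kept in each leave-one-out fit: those of Fdft1, Hk1, Hk2, Tet3, Polr2a and Sdha. All others were lost without GFP-negative M, and all of these but Insig1 and Zmat3 also without GFP-positive 7. Ddit4, Sesn2, Peg3, Airn, mt-Nd3 and Mid1 did not pass without GFP-positive 2. Without GFP-positive 4 the calls of Msmo1, Vldlr, Cdkn1a, Peg3, Airn, Xaf1, mt-Nd3, Rlim and Ppia were lost, and without GFP-negative 11 those of Vldlr, Sesn2, Peg3, Airn, Hoxb6, Xaf1 and mt-Nd3, the last with a log2 change of 1.95. After removal of the length trend Zmat3 (-0.66), Vldlr (-0.54), Rlim (-0.48), Peg3 (-0.59), Igf2r (-0.56), Airn (-0.54), Sesn2 (-0.91), Pmvk (0.93), Ppia (1.06), Hoxb6 (1.11), Xaf1 (1.59) and mt-Nd3 (2.03) did not pass. For named transcripts only, neither did Zmat3 (-0.68), Vldlr (-0.93) and Xaf1 (1.47). Quantile normalization ended the calls of Airn, Hoxb6, mt-Nd3 and Ppia (0.60), and leaving FPKM as deposited that of mt-Nd3. Scaled to an equal sum Insig1, Pmvk, Msmo1, Suv39h1, Ndn, Xaf1, Ppia and mt-Nd3 did not pass. With no filter Pfkl, Pmvk, Msmo1, Herpud1, Ddit4, Vldlr, Sesn2, Peg3, Airn, Xaf1, Hoxb6, mt-Nd3, Rlim, Mid1, Eef2 and Ppia did not pass.

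In total 6 of the 25 lists tested passed with the preset correlation, 4 passed in fry (all but the proliferation and matrix lists) and none with an estimated correlation. No chromosome passed among 22. The median log2 difference was 0.62 for the 30 tested genes of chromosome Y (camera adjusted p = 0.851), 0.29 for chromosome X and 0.30 for chromosome 13 (both adjusted p = 0.185), and lay between -0.14 and 0.30 for the autosomes. Of the 30 Y genes 10 rose and 2 fell. They include Rbmy and neighbouring copies that share its reads, such as Gm21708 (1.67) and Gm21693 (1.38), which supplied most of the rises. Among the 23 genes without these, more lay lower than higher in the GFP-positive libraries. Many of the lower ones lay in a stretch from 90728862 to 90855309, and outside it lower genes did not outnumber higher ones. The rises outside the copies were Gm2098 (2.22), Uba1y and Ddx3y. The falls were the new loci MSTRG.22797 (-1.43) and MSTRG.22802 (-1.03), both in that stretch, on either side of Mid1-ps1 (-0.79). Whether reads there are shared with Mid1 on chromosome X, which also fell, was not tested.

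Fold changes followed transcript length. Across genes, which are not independent replicates, Spearman's rho between log2 fold change and the length of the main transcript was -0.49. The median log2 fold change was 1.13 for the 1146 genes of 200 to 500 nt and -0.62 for the 1047 genes of 8000 nt or more. Each GFP-positive library had a negative relation of its deviation with length (rho -0.282, -0.471 and -0.459) and each GFP-negative library a positive one (0.383, 0.336 and 0.437). Deviations were taken from the mean of the same 6 libraries, so opposite signs in the groups are partly built in. Within the GFP-negative group, the difference of 9 from the mean of 11 and M had a rho of -0.11 with length. With the length trend removed 2310 genes passed, of which 1766 were among the 4639 with the same direction.

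**Figure D4:**
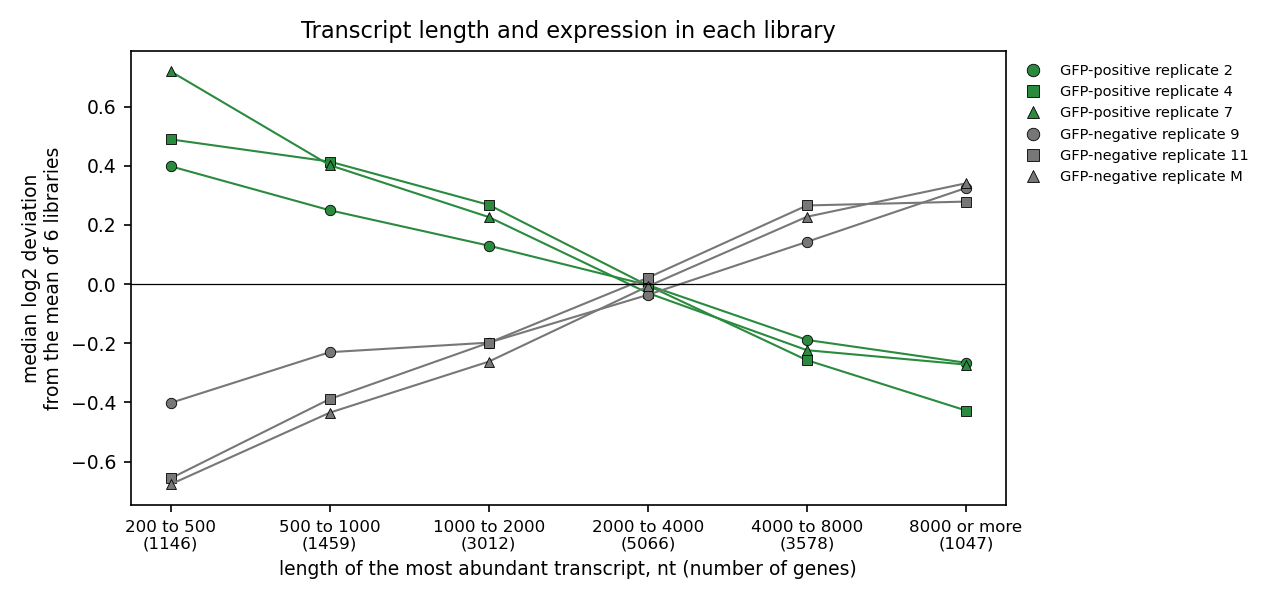
Median log2 deviation from the mean of 6 libraries against the length of the most abundant transcript (nt, with the number of genes), a line per library. GFP-positive libraries lie above 0 for transcripts of 200 to 500 nt and below 0 for those of 8000 nt or more, and GFP-negative libraries the reverse.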

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

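The summed level of the 1205 genes under 200 nt, which were left out of the tests, was higher in the GFP-positive libraries. It averaged 163.4 ± 6.33 (SD, n = 3) scaled FPKM there and 101.9 ± 4.32 in the GFP-negative libraries, a ratio of 1.6 (exact permutation p = 0.1, the smallest the design allows). The libraries stood at 163.8, 156.9 and 169.6 against 97.8, 106.4 and 101.4. FPKM of RNAs this short is unreliable.

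The tests below had their predictions written before the result, except that of germ cells as the source of the Y gene difference, written after it. The length trend was itself noticed in these data.

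The first pattern is the rise of germ cell genes. Removing the length trend left the median of the germ cell markers at 2.31, with 8 of 11 past the threshold, so that trend is not the whole cause. Germ cells in the GFP-positive cultures predicted a median over 1 for spermatogonial genes whose values had not been seen and that lie outside a list of methylation-controlled genes, and the median of those 17 genes was 1.18. The bootstrap interval of that median, taken over genes and not libraries, ran from -0.007 to 1.65. That also takes in the range predicted without germ cells. Members of the spermatogonial list varied together (estimated inter-gene correlation 0.32), so the interval is likely too narrow. Of the 17 genes 12 lay above 0, 7 rose, and Foxo1 and Ccnd3 fell. Of 38 listed spermatogonial genes, 8 had a mean of at least 0.5 FPKM in GFP-negative and 30 in GFP-positive libraries, so the filter favoured a high median. Release of methylation-controlled genes alone, which predicted a median under 0.5, cannot be told apart by the same value (1.18) because of that interval, and a change in the Sertoli cells themselves stays open.

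The second pattern is the relation of the gene lists to transcript length. Among 10000 random lists matched on length and level, the median of the ribosomal protein genes stood at the 35.6 percentile, so the length trend may account for their rise in part; with it removed 4 rose and the list still passed (median 0.62, camera adjusted p = 0.0371), so whether it accounts for the whole stays open. The histone genes stood at 99.91, the proliferation genes at 100, the matrix genes at 0 and the protocadherin genes at 0.97. Each lay beyond what length and level gave for genes drawn independently. Members of these 4 lists varied together (estimated inter-gene correlation 0.41, 0.45, 0.28 and 0.16), which widens the spread of a list median. The random lists do not allow for that, so these percentiles cannot decide whether length and level account for the changes. The protocadherin call ended once length and GC trends were removed together (median -0.80, SD over members 0.57, before and -0.32, SD 0.49, after; camera adjusted p = 0.0773) because the members moved towards 0, so a joint effect of both stays open for that list. The called genes Hspg2, Fn1, Col1a1, Myh11, Actg2 and Pdgfrb shared an order among the GFP-negative libraries, which was not counted over their whole lists. The first principal component and genes of no such cell type, such as Eef2, had that order too. Whether other cell types in those cultures carry the matrix difference was not tested. Whether the length trend itself came from RNA quality, library preparation or the cells was not tested.

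The third pattern is the higher level of Y single-copy genes. With the length trend removed their mean difference was 1.39, against 1.05 before, so length does not account for it. If germ cells carried the difference, the broadly expressed genes Ddx3y, Eif2s3y, Kdm5d and Uty were predicted to differ by under 0.5. They differed by 0.68 (SE 0.43) with overlapping groups, so germ cells and a difference in Sertoli cells cannot be told apart at this spread.

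The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4639 called genes and the highest of the others 0 (1 split reached the real count). For gene lists at the preset correlation the real split gave 6 and the highest other 14, and 9 of the 10 splits gave at least as many as the real one, so these list calls are no more numerous than for other groupings of the libraries. For chromosomes the real split gave 0 and the highest other 3, so all 10 reached it.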

How the results depend on the processing

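Alternatives named as added were chosen after seeing the data; the others were planned. The count of called genes (4639) was within 1.5 times under 15 of 26 alternatives. It was 1756 with no filter, 7931 scaled to an equal sum, 2122 for transcripts tested on their own, and 538 to 6206 with a library left out. Among added alternatives it was 2310 with the length trend removed, 9195 with gene-by-gene library weights, and 0 in limma without GFP-negative 11 and M, where 3677 had an unadjusted p under 0.05 and the lone GFP-negative library was assumed to vary like the others. The planned library weights gave 12265, but their estimation stopped before converging with a weight of 44.2 for GFP-negative M, so that count is no usable estimate. No gene called in both the main and an alternative fit changed direction where genes were matched. The Y list difference (1.05) was 0.39 scaled to an equal sum and 0.52 without GFP-negative 11 and M. With a library left out it ran from 0.75 to 1.33. Chromosomes past the threshold (0) were 1 with no filter (X), 3 scaled to an equal sum (13, X and Y, above a median of all genes at -0.86) and 1 without GFP-negative 11 and M (mitochondrial). Lists past the threshold (6) were 0 with an estimated correlation, and 5 to 8 with a library left out. The mitochondrially encoded list turned lower without GFP-negative 11 and M (adjusted p = 0.000222, n = 4 libraries, limma's camera), and Ndn stood at -0.062 scaled to an equal sum. Apart from these, the cause was not tested where the construction does not show it. Camera has no robust option, so lists and chromosomes have no value for it. Of values of named genes under the alternatives, 1871 kept direction and side of the threshold, 320 were no longer past it, 19 newly passed and 1 reversed. Depth is known as total aligned bases, not reads per gene, so the counting error of low genes is unknown.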

Other observations

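The lists in the next paragraph, and the genes named in both, were chosen after the first results were seen.

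Germline genes beyond the fixed markers were higher in the GFP-positive libraries. Of 27 tested genes known to be silenced by DNA methylation in somatic cells, 24 rose and none fell (median log2 change 2.37). They include Dazl, Mael, Tex101, Taf7l, Tex19.1 and Asz1, which are among the 12 largest rises named above. Members such as Nxf2 (20.2, 1.37 and 4.96 FPKM in GFP-positive 2, 4 and 7) and Rnf17 (11.4, 1.71 and 3.32) were highest in GFP-positive 2. Of 17 meiotic prophase genes 11 rose (median 1.56), among them the synaptonemal complex genes Syce3 (3.05), Syce1 (2.5) and Sycp3 (2.01). Of 24 spermatogonial genes 12 rose and 2 fell (median 1.42), with Sohlh2 (3.13), Dnd1 (2.96) and Crabp1 (2.75) among the rises. With the length trend removed 5 meiotic genes rose (median 1.41), against 24 methylation-controlled (median 2.23) and 12 spermatogonial genes (median 1.55). With an estimated correlation each list had a camera adjusted p of 0.219. Of 27 spermatid genes 2 were above the filter, and Odf2 fell (-1.28) while Zpbp did not pass (0.83). The lists overlap: 6 methylation-controlled, 5 spermatogonial, 2 meiotic and 5 spermatid genes are also among the 20 fixed germ cell markers. The meiotic list shares 4 genes, Syce1 and Sycp3 among them, with the methylation-controlled list and 1 with the spermatogonial list, so these rises are not separate evidence. In the GFP-negative libraries 8 of 38 spermatogonial genes had a mean of at least 0.5 FPKM, against 30 in the GFP-positive libraries. These counts were 3 and 28 of 30 methylation-controlled genes, and 5 and 19 of 27 meiotic genes. Most members thus passed the filter through the group where they were high, which largely fixed the direction of their change in advance.

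A few short, abundant RNAs took a larger part of FPKM in the GFP-positive libraries. The annotated transcript of Rpph1, the RNA of ribonuclease P, stood at 60619, 41617 and 38248 deposited FPKM in GFP-positive 2, 4 and 7 and at 19761, 6157 and 7862 in GFP-negative 9, 11 and M. MSTRG.6396.3, an unnamed transcript over the same bases and strand that was left out of the gene sums because its locus holds more than 1 gene name, stood at 17473, 33169 and 41273 against 15051, 1594 and 2966, so how reads were shared between them is unknown. Rmrp stood at 36572, 41042 and 41948 against 16927, 4156 and 5658. The most abundant transcript, the unnamed MSTRG.4501.1 (582 nt), stood at 127573, 217833 and 181593 against 85904, 15535 and 27130. An abundant long transcript, the unnamed MSTRG.9014.2 (chromosome 17, 40153887 to 40159723, 5786 nt), went the other way on average. It stood at 2190, 6607 and 7101 against 6688, 31331 and 17769, so GFP-negative 9 lay between GFP-positive 4 and 7. What RNA this transcript is was not determined. Whether ribosomal RNA removal differed between the libraries, with GFP-negative 11 and M apart, was therefore not tested. The sum of FPKM over a library was 668557, 747404 and 723729 against 470070, 292449 and 309971.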
